A study of Escherichia coli with 2 samples.

How the data were processed

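The series holds 2 two-colour oligonucleotide arrays of Escherichia coli K-12 BW25113, each of 1 biological replicate and without a dye swap. Per the labels, the first array set the rodZ deletion strain with the empty expression vector pCA24N (Cy5) against the wild type with the same vector (Cy3), and the second set the deletion strain carrying pCA24N-RodZ (Cy5) against the deletion strain with the empty vector (Cy3). Cultures of 250 ml LB were grown at 37 °C to an OD600 of 0.5 and kept with 1 mM IPTG, the inducer of the plasmid's promoter, for 6 h. The labelling protocol in the labels names a knockdown of another gene, which is not part of this series.

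Each deposited table has 4250 probes of 45 to 47 bases, 1 per locus tag. Per the file headers it gives, for each condition, a raw intensity, a spot flag, a normalized log2 value and a fold between the conditions. The raw intensity deposited by the authors had been averaged over spots and reached below 0, so a background had been taken off before. How it was measured is not given in the sources used here. The deposited flag score lay between -50 and 0 in steps that fit 4 spots per probe, each found (0) or not found (-50), and a raw value was missing where no spot was found. The deposited normalized log2 intensities were close to a straight line of log2 of the raw values, with slopes of 1.08 for the wild type, 1.00 for the deletion and 0.988 for the RodZ plasmid strain, and the largest residual over the 3 conditions was 0.00577. The deposited fold ratio by the authors counted a condition without a value as 1, which gave folds of up to 11747. The highest deposited fold, 23170, was that of cheZ, chosen after its values were seen, with a raw intensity of -10 in the wild type. The deposited series matrix held log2 of these fold ratios, with a largest difference of 5e-05. The tables also held 3 value columns each that were not used.

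All 4250 probes had the same rodZ/pCA24N values in both tables. The tables therefore held 3 measured conditions, and the deletion strain entered both comparisons as 1 shared measurement. Which of the 2 arrays, and so which dye, this measurement came from is not given in the sources used here. If it came from 1 array, 1 of the 2 comparisons set conditions from different arrays against each other, and which one is not known. The comparison of the deletion strain between arrays that was planned before the data were examined could not be made.

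The planned processing assumed spot foregrounds and backgrounds, which the tables do not hold. In its place, an offset of 50 was added to the raw intensity, log2 was taken, and the log2 ratio of a pair of conditions was centred on a lowess curve over mean log2 intensity (span 0.3, 3 iterations). A gene counted as detected in a condition when at least 3 of its 4 spots were found, a rule chosen after the tables were read. A gene detected in both conditions had a measured ratio. A gene detected in 1 of them had under 3 spots found in the other and could have a bound. The bound set the value of the detected condition against the higher of the other value and a floor. The floor was the lowest raw intensity among probes with all 4 spots found in that other condition. It was 21.75 for the wild type, 32.25 for the deletion and 55.25 for the RodZ plasmid strain. Where no spot was found the floor stood alone, so such a bound assumes a signal at or below it. The rule counts spots and not brightness: cheZ read 23149.5 in the deletion with 2 spots found. A bound was kept only where it put the detected condition higher, so each bound gives a direction. Otherwise the gene had neither a ratio nor a bound. This held for 181 genes in the deletion over the wild type and 190 in the RodZ plasmid strain over the deletion. It held for 149 in the RodZ plasmid strain over the wild type. Genes detected in neither were not compared.

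With 1 measurement per condition there were no residual degrees of freedom, so no test was made, no p-value is given and no ratio has a replicate error. Genes were described by size, at least 2-fold. For 40 gene lists fixed before the data were examined, the median log2 ratio of the measured members (at least 3) was placed among 10000 random lists of the same size, matched in 20 bins of mean intensity, as a description of these arrays. Lists rotated along the order of locus tag numbers, which need not be the genome order for every gene, were used as well. Of 720 list entries, 5 had no probe. Named genes followed a rule fixed in advance: the 12 highest and 12 lowest measured ratios of at least 2-fold per comparison, up to 4 members per list with the largest ratio, 10 genes that were opposite and 5 that were alike in the 2 comparisons, and always rodZ, its neighbours and the genes of the elongation complex. A few others were added after their values were seen, as said beside them. A further pairing, the RodZ plasmid strain over the wild type, was added after the tables were read. Its conditions were, per the labels, hybridised on different arrays, which may hold for 1 of the 2 main comparisons as well.

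Gene names came from a RefSeq gene table of assembly ASM584v2, which held 4241 of the 4250 locus tags. The current symbol differed from the name in the tables for 488 of them. The genome build behind the probes is not given in the sources used here, so no coordinates are printed and the table served only for names and for which genes are neighbours.

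Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The procedure was tested on simulated data for the comparison of the rodZ deletion with the wild type over 1454 genes, with an intensity-dependent bias and 200 changed genes. All 50 genes changed 4-fold were called, as were those changed 8-fold and 16-fold, and 15 of 50 changed 2-fold. None of 1254 unchanged genes was called. The simulated noise was smaller than the spread of the observed ratios, and every simulated gene had all 4 spots found. The run therefore gives no rate of false calls for these arrays and did not try the bounds. The median simulated 4-fold ratio was 1.72 on the log2 scale, so the offset and the curve understate sizes. Of 200 unshifted simulated lists, 6.5% fell outside the central 95% of random lists, and 100% of 50 lists shifted by 0.5 fell above it. Alternatives covered the offset, the scaling, the detection rule, the authors' values, the size threshold, the probes used and the random lists.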

Results

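Gene expression was measured on oligonucleotide arrays in 3 strains of Escherichia coli K-12 BW25113, a laboratory strain from which the Keio collection of single-gene deletions was built. RodZ is a membrane protein of the rod complex, which works with the actin-like MreB to give the cell its rod shape, and the series asks how cell shape relates to biofilm formation. The strains were the wild type with the empty vector pCA24N, a rodZ deletion with the empty vector, and the rodZ deletion with the same vector carrying rodZ. Each strain gave 1 measurement, so no ratio below has a replicate check, and the number of arrays limits the precision. At least 3 of 4 spots were found for 1658 of 4250 genes in the wild type (39.0%), for 1910 in the deletion (44.9%) and for 1483 in the RodZ plasmid strain (34.9%). The median raw intensity of detected genes was 284 in the wild type, 373 in the deletion and 437 in the RodZ plasmid strain.

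The targeted gene followed the labels. The rodZ probe, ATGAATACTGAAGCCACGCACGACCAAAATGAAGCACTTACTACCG, read 256 in the wild type with 4 spots found, 3 in the deletion with 1 spot found, and 700 in the RodZ plasmid strain with 4 spots found. It was at least 4.57-fold lower in the deletion than in the wild type, and at least 11.2-fold higher in the RodZ plasmid strain than in the deletion. The labels do not say which part of rodZ was deleted. The RodZ plasmid strain had a log2 ratio of 0.95 for rodZ over the wild type. The downstream neighbour ispG, which encodes an enzyme of isoprenoid synthesis, read 244 in the wild type, 925 in the deletion and 2005 in the RodZ plasmid strain. Its log2 ratio was 1.21 for the deletion over the wild type and 1.33 for the RodZ plasmid strain over the deletion. The ispG probe holds the word CTCC or CCTC, described below. Of the other neighbours, bamB, der and hisS gave neither a ratio nor a bound in either comparison. rlmN read 232 with 4 spots found in the deletion, at least 1.76-fold above the wild type, and had under 3 spots found in the other strains. yfgM read 239 with 3 spots found in the RodZ plasmid strain, at least 2.79-fold above the deletion and with a log2 ratio of 1.18 over the wild type. In the elongation complex, mrdA had a log2 ratio of -0.37 for the deletion over the wild type. mreB was detected in the deletion alone, where it read 168, at least 2.57-fold above the wild type. mreC read 80.5, 180 and 181 in the wild type, the deletion and the RodZ plasmid strain, with 2, 3 and 3 spots found. mrdB was detected in the deletion alone, where it read 73.7, and mreD in no strain.

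The first comparison asked what the loss of RodZ changed. All 7 curli genes, which build and regulate the amyloid fibres that hold biofilm cells together, were at least 2-fold lower in the deletion. Their median log2 ratio was -1.78, below all of 10000 random lists (central 95% from -0.54 to 0.63). The minor curli subunit csgB had a log2 ratio of -3.33, csgC -2.96, csgE -2.18, the regulator csgD -1.78 and the major subunit csgA -1.49. Of the phage shock genes, which respond to damage of the inner membrane, 5 of 6 measured members were at least 2-fold lower, with a median of -1.71 (random lists from -0.61 to 0.60). pspC had a log2 ratio of -3.17, pspB -2.77, pspD -1.91 and pspG -1.51. Genes of the general stress response under sigma S had a median of -0.70 over 23 measured members (random lists from -0.34 to 0.38), 5 of them at least 2-fold lower and none 2-fold higher. By bound, yciE was at least 3.06-fold and yciF at least 2.17-fold lower, both chosen after their values were seen. Among the measured members were osmY at -1.50, sodC, a periplasmic superoxide dismutase, at -1.23 and osmC at -1.14.

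**Figure D1:**
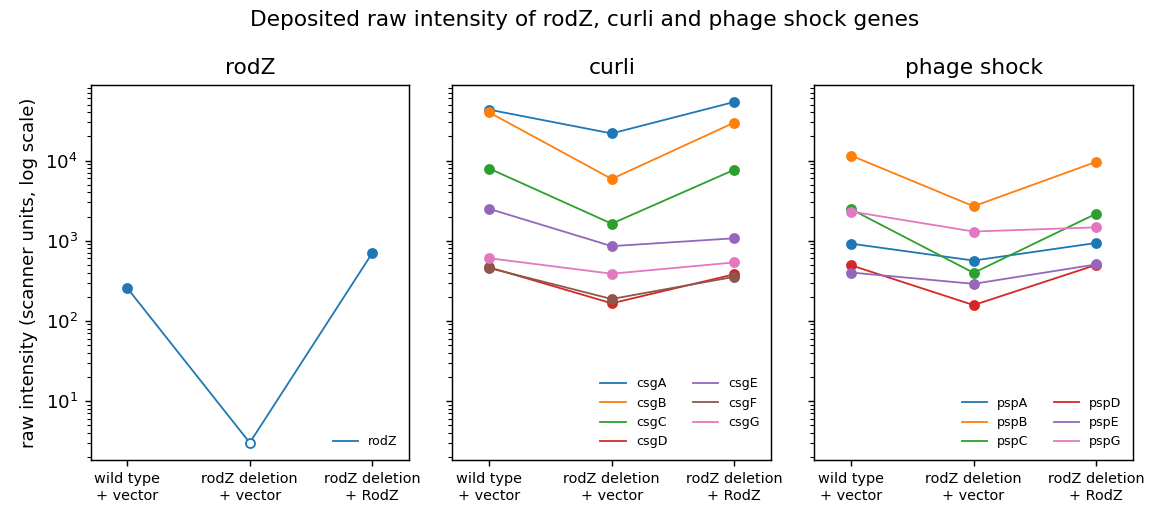
Raw intensity in scanner units, on a log axis, of rodZ, the 7 curli genes and the 6 detected phage shock genes in the 3 strains. Each point is 1 measurement averaged over the spots found, without error bars; the open point marks a gene with under 3 of 4 spots found. rodZ read 256, 3 and 700, and csgB read 39990, 5903 and 29822 in the wild type, the deletion and the RodZ plasmid strain.

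Ribosomal protein genes lay on the other side. Their median was 0.49 over 52 measured members (random lists from -0.24 to 0.29), 50 of them above 0 but only 1, rpsF at 1.03, at least 2-fold higher. By bound, rplY was at least 4.05-fold higher, a gene chosen after its values were seen. The 7 measured genes of ATP synthase, which makes ATP from the proton gradient, were all above 0, with a median of 0.84 and atpH highest at 1.10. Genes of the tricarboxylic acid cycle had a median of 0.52 over 11 measured members, with sucB at 1.26, acnB at 1.19 and sucC at 1.14. In the list of sugar uptake systems, 5 of 16 measured members were at least 2-fold higher and 2 at least 2-fold lower, the lowest at -1.26. The members named by size were galactitol genes, which had no list of their own: gatB at 2.32, gatA at 1.83, gatY at 1.66 and gatC at 1.52. The list's median of 0.31 lay inside the random lists, and outside them with no filter on dim spots (0.38, percentile 98.4). Regulators and adhesins linked to biofilms had a median of -0.49, at percentile 2.80 of random lists, inside the central range, but outside it among rotated lists (0.86), with no filter on dim spots (0.69), with all 4 spots required (1.52) and in the series matrix values (0.98), and 2 of its 11 measured members were at least 2-fold lower, bssR at -1.69 and bssS at -1.46. The sigma S cofactor gene crl was higher, at 1.11. Genes of peptidoglycan synthesis and remodelling had a median of 0.23 over 11 measured members, inside the random lists, with ldtD, which encodes an enzyme that crosslinks the cell wall, at -1.33. Of the 11 members, 7 lay above 0, and 6 had probes holding CTCC or CCTC. Without such probes the median was -0.92, opposite in sign and at percentile 0.06. It then rested on few genes, among them ldtD, ldtC at -0.94 and ldtE at -0.93. With no filter on dim spots the median was 0.32 at percentile 99.1, so these alternatives lay outside the random lists on opposite sides. Cell division genes had a median of 0.27 over 9 members, also inside, and outside with no filter on dim spots (0.38, percentile 98.0) and in the series matrix values (0.69, percentile 99.5). Of 28 lists with enough measured genes, 6 fell outside the central 95% of random lists, and 7 that of rotated lists, where chance gives 1.4. None of 39 flagellar genes was measured in both strains, and 1, flgG, was at least 3.57-fold lower by bound, a gene chosen after its values were seen. Of 13 chemotaxis genes, 9 type 1 fimbria genes and 21 colanic acid genes, 1 each was measured.

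In all, 157 genes were at least 2-fold higher and 85 at least 2-fold lower in the deletion, of 1933 genes with a ratio or a bound. The highest measured ratios were those of ddpA, which encodes a D-alanyl-D-alanine transport protein, at 4.06, the zinc-binding protein gene zinT at 3.85, iap at 3.02 and ypjA at 2.82. emrA, a component of a multidrug export pump, was at 2.80, the ribose gene rbsD at 2.53 and the lipopolysaccharide assembly gene lptD at 2.22. Beside curli and phage shock genes, the lowest ratios were those of the magnesium transporter gene mgtA at -3.14, ygfF at -2.62, ymdF at -2.23, mcbA at -2.16, the methylcitrate synthase gene prpC at -1.96 and the osmotically induced lipoprotein gene osmB at -1.87. The ymdF probe carries a cross-hybridisation note in the tables. Among genes measured in both strains alone, 72 were higher and 67 lower. Without scaling, the median log2 ratio of all genes was 0.50, and 456 genes were higher and 27 lower, so each ratio is relative to that shift.

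The second comparison asked what the RodZ plasmid changed in the deletion strain. The curli and phage shock genes were higher. All 7 curli genes had a log2 ratio above 0 and 5 were at least 2-fold higher, with a median of 1.33 (random lists from -0.47 to 0.71). csgB had a log2 ratio of 2.56, csgC 2.51, csgA 1.48 and csgD 1.33, while csgE was at 0.54. All 6 measured phage shock genes were above 0 with a median of 1.32, and 3 were at least 2-fold higher, pspC at 2.55, pspB at 2.09 and pspD at 1.72. With all 4 spots required, the phage shock median of 0.94 fell inside the random lists. Enzymes that make or break down the second messenger cyclic di-GMP had a median of 0.67 over 8 measured members, at percentile 99.2, and 3 were at least 2-fold higher, dgcC at 2.82, dgcZ at 1.13 and pdeC at 1.11. That list fell inside the random lists without the filter on dim spots (0.32, percentile 88.5), with all 4 spots required (0.23, percentile 75.1) and in the series matrix values (-0.084, percentile 90.4, where the median of all genes was -0.76). The biofilm-linked list had a median of 0.56 at percentile 95.2, inside the central range, but outside it among rotated lists (98.5) and with no filter on dim spots (98.0). It had 6 members above and 5 below 0, with bssR at 1.97 and bssS at 1.13. The periplasmic stress gene cpxP was at 2.06 and the gene of the envelope stress sigma factor, rpoE, at 1.61, in a list whose median of 0.27 lay inside the random lists.

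**Figure D2:**
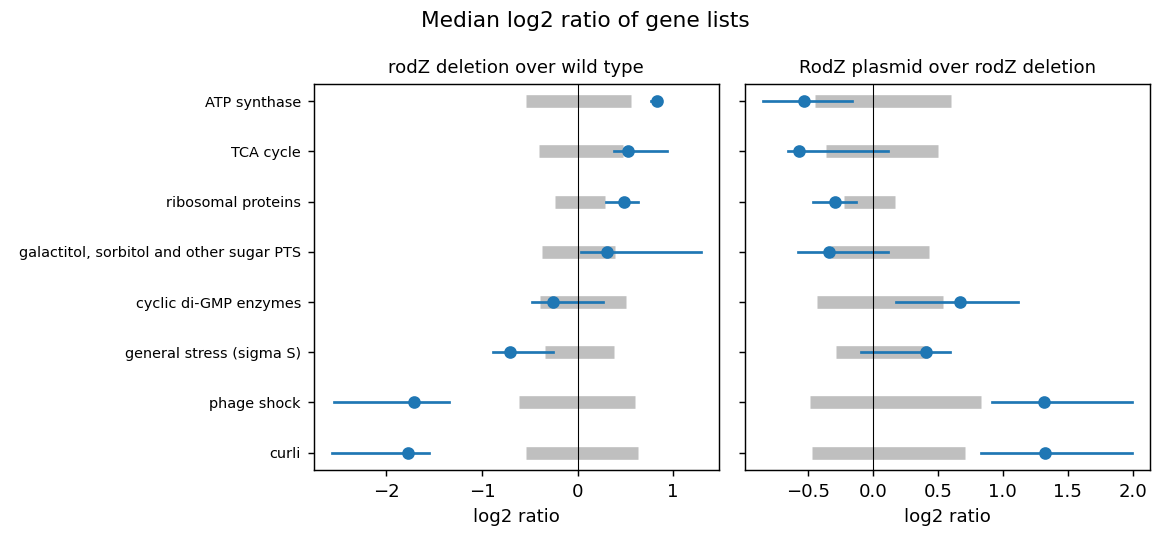
Median log2 ratio of the 8 gene lists outside the central 95% of random lists in either comparison. Points are medians over measured members, blue lines the range from the lower to the upper quartile of members, and grey bars the central 95% of 10000 random lists of like intensity; the panels have different scales. The curli median was -1.78 in the first panel and 1.33 in the second, and the ribosomal protein median 0.49 and -0.29.

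Ribosomal protein genes had a median of -0.29 in this comparison, with 45 of 53 members below 0 and 3 at least 2-fold lower, among them rplI at -1.08 and rpmH at -1.04. Tricarboxylic acid cycle genes had a median of -0.57 over 13 members, though aceA, the isocitrate lyase gene of the glyoxylate shunt, was at 1.43. ATP synthase genes had a median of -0.53 over 9 members, with atpF lowest at -1.62. Without probes that hold the words CTCC or CCTC, the ATP synthase median was -0.27, inside the random lists. The sugar uptake list had a median of -0.34, at percentile 2.17, with mtlA at -1.38, gatZ at -1.22 and gatY at -1.17. It lay inside the central range in 5 alternatives, among them median centring (2.53) and the series matrix values (18.5). The sigma S list had a median of 0.41 at percentile 97.0, inside the central range, but outside it among rotated lists (percentile 99.3), with no filter on dim spots (98.5) and in the series matrix values (98.4, with a median of 0.041). Of 29 lists, 7 fell outside, and 9 among rotated lists, where chance gives 1.45.

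In all, 170 genes were at least 2-fold higher and 141 at least 2-fold lower with the RodZ plasmid, of 1833 genes with a ratio or a bound. Among genes measured in both strains alone, 137 were higher and 73 lower. The others, 33 higher and 68 lower, rested on bounds. The highest measured ratios were those of dsrB at 5.57, the xanthine transporter gene xanQ at 4.45, cybB, a cytochrome gene, at 4.41, the cell division gene ftsW at 3.86, iraM, whose product stabilises sigma S, at 3.56, yoeA at 3.49 and yhiS at 3.18. The probes of xanQ, ftsW, iraM, yoeA and yhiS hold the words CTCC or CCTC, as do those of ispG, zinT, iap, emrA, lptD, gatB, gatC, csgA, csgC, bssR, dgcC, ftsN, frlR, ylcH, atpF and mtlA. Genes with such probes had a mean log2 ratio of 0.35 in this comparison against 0.0087 for the others, and 0.087 against -0.013 in the first comparison. These means include the probes of odd number, among which the words led. Among probes of even number the difference was 0.25 in this comparison (bootstrap interval from 0.077 to 0.42). In the first comparison it was 0.0012 (from -0.12 to 0.13), so no effect of the words was seen there. Other genes of the division list were lower in size, with ftsN at 1.70 and a list median of 0.23, inside the random lists. In the series matrix values the list lay outside them at percentile 99.0, with a median of -0.068, where the median of all genes was -0.76. The lowest were ddpA at -4.19, the porin gene ompF at -2.82, yiaN at -2.31, cvpA at -2.15, ylcH at -1.87, the gluconeogenic enzyme gene pck at -1.85 and the putrescine-binding protein gene potF at -1.84. The zinT probe had no spot found in the RodZ plasmid strain. It was at least 76.9-fold lower there than in the deletion if its signal lay at or below the floor of 55.25. Without scaling, the median log2 ratio was -0.26, with 109 genes higher and 258 lower. The authors' normalized values gave 118 higher and 473 lower, around a median of -0.41.

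The comparisons were then set side by side to ask which changes of the deletion went the other way with the plasmid. Of 1684 genes with a ratio or bound in both, 38 were higher in the deletion and lower with the plasmid and 33 were lower in the deletion and higher with the plasmid. Independent lists would share 12.2 and 5.94. In like direction, 17 genes were higher in both and 1 lower in both, against 12.2 and 5.94. Without probes holding CTCC or CCTC, 6 genes in place of 18 were alike. The opposite genes with the largest changes in both were ddpA, ygfF, csgB, pspC, csgC, ymdF, pspB, frlR, yiaN and yncJ. Among the genes alike were lptD, gspC, iap, emrA and ftsW, of which all but gspC have such probes. Across 1210 genes measured in all 3 strains, which are not independent replicates, the log2 ratios had a Pearson r of -0.23 and a Spearman rho of -0.20. The deletion measurement stands in both ratios, and this alone makes them opposite: simulated unchanged strains that share it gave a mean r of -0.50, and 2.8e-05 where its noise was drawn separately. The observed covariance was -0.12 against a simulated -0.27. With the deletion measurement shared, simulated unchanged strains gave a mean of 65.7 opposite genes and 1.09 alike, where 45 and 16 of the measured genes were seen. The simulated noise was set from the spread of the observed ratios and was equal in the 3 strains, so real changes were counted as noise. The simulations show the direction that sharing gives, and not how much of the observed opposition is error.

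**Figure D3:**
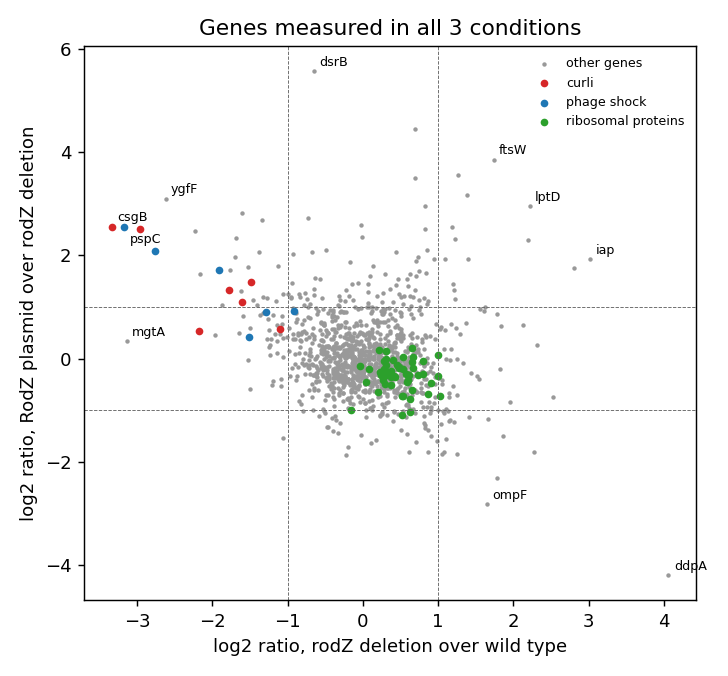
Log2 ratio of the RodZ plasmid strain over the deletion against that of the deletion over the wild type for 1210 genes measured in all 3 strains, 1 point per gene. Dashed lines mark 2-fold. csgB lies at -3.33 and 2.56, pspC at -3.17 and 2.55, ddpA at 4.06 and -4.19, and lptD at 2.22 and 2.95.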

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

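The detection rule and the alternatives that use the authors' normalized log2 values, all 4 spots, a lowess span of 0.6 or fewer probes were chosen after the tables were read, as was the pairing of the RodZ plasmid strain with the wild type. No paired analysis was possible because each condition had 1 measurement and no test was made. No uncorrected foreground, pixel summary, print-tip layout or single spot value was held in the tables, so no background correction, mean against median pixels, print-tip loess and agreement of duplicate spots were not run. The normal-exponential correction with offset 0 came down to the run with offset 0. The rodZ bounds of -2.19 and 3.49 stayed beyond 2-fold in every alternative run. Over the genes and lists named, 6409 gene values kept their side of the 2-fold line, 345 passed it and 111 fell back. Of the list values, 935 kept their side of the central range, 27 left it and 36 entered it. A further 3 list values entered it with the opposite sign.

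The count of 242 genes for the deletion over the wild type was 397 with offset 0, 483 without scaling, 389 with no filter on dim spots, 139 for genes detected in both conditions, 1567 in the series matrix values and 434 in the authors' normalized values, and 648 and 80 at the 1.5-fold and 3-fold thresholds. Of the 1567, 904 had no value in 1 condition, which the authors had counted as 1. The count of 311 genes for the RodZ plasmid strain over the deletion was 439 with offset 0, 437 with no filter on dim spots and 367 without scaling. It was 210 for genes detected in both conditions and 213 without probes holding CTCC or CCTC. In the series matrix values it was 1876 and in the authors' normalized values 591. At the 1.5-fold and 3-fold thresholds it was 691 and 99. For the RodZ plasmid strain over the wild type, 380 became 580 with no filter, 206 for genes detected in both, 2119 in the series matrix values, 744 in the authors' normalized values, 252 without probes holding CTCC or CCTC, and 781 and 153 at the 2 thresholds. The 71 opposite genes became 128 without scaling, 45 for genes detected in both conditions, 681 in the series matrix values, 129 in the authors' normalized values, and 199 and 23 at the 2 thresholds. The correlation of -0.23 was -0.36 in the series matrix values and -0.44 without probes holding CTCC or CCTC. With no filter on dim spots, 11 lists in place of 6, and 11 in place of 7, lay outside the central 95%. For the RodZ plasmid strain over the wild type, 8 lists became 4 with median centring, 4 without scaling, 4 in the series matrix values, 5 in the authors' normalized values and 3 with all 4 spots required. The rodZ log2 ratio of 0.95 in that pairing was 1.07 with offset 0, 1.29 without scaling and 1.02 with all 4 spots. It was 0.69 both in the series matrix values and in the authors' normalized values. In the series matrix values, whose median over all genes was -0.76 for the RodZ plasmid strain over the deletion and -0.83 over the wild type, the cyclic di-GMP list was -0.084 (percentile 90.4) in the first and the iron and prophage lists -1.32 and -1.53 (percentiles 9.34 and 11.6) in the second of these. Spots not found limited the rest: 2592, 2340 and 2767 of 4250 genes were not detected in the wild type, the deletion and the RodZ plasmid strain.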

Other observations

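The gene lists in this part were fixed before the data were examined. The tests of explanations were chosen after the values were seen. The pairing of the RodZ plasmid strain with the wild type, whose conditions were on different arrays, showed how far the plasmid strain stood from the wild type. The curli median was -0.59, at percentile 2.37 of random lists, and inside their central range in 7 alternatives, such as median centring. All 6 measured phage shock genes were below 0, with a median of -0.41 at percentile 4.53. The sigma S list had a median of -0.36, at percentile 0.94, with no member at least 2-fold changed, and lay inside the central range in the series matrix values (percentile 4.02). mgtA stayed low in both rodZ strains, with a log2 ratio of -2.80 over the wild type. Iron uptake genes had a median of 0.96, above all of 10000 random lists (central 95% from -0.40 to 0.47), with fepB at 2.47, fecE at 1.97 and exbD at 1.57. With all 4 spots required, that median was 0.40, inside the random lists, and in the series matrix values it was -1.32, inside at percentile 9.34, where the median of all genes was -0.83. Outer membrane porins and lipoproteins had a median of -0.71 over 9 measured members, with ompF at -1.13, and fell inside the random lists with no filter on dim spots (-0.44, percentile 3.18) and in the series matrix values (percentile 4.06). Also outside were the prophage list (0.79, percentile 98.6), cell division (0.61, 98.3), the rodZ locus (1.18, 98.7) and anaerobic respiration (-0.63, 2.38). Each of these lay inside in some alternatives. The prophage list did so without probes with a cross-hybridisation note (0.34, percentile 76.1). Of 7 genes on the list of those deleted in BW25113, lacZ read 696 in the wild type, 1159 in the deletion and 517 in the RodZ plasmid strain, all with 4 spots found. araD, chosen after its values were seen, was detected in the RodZ plasmid strain alone, where it read 180 with 3 spots found, at least 3.47-fold above the deletion. It was not called 2-fold above the wild type. Where the lacZ and araD probes lie relative to the deleted parts is not given in the sources used here. If the araD probe lies inside, a gene without a transcript passed both the detection rule and the 2-fold bound. The bound of mreB rests on a like intensity. lacI, which pCA24N also carries, read 9741, 21861 and 9981.

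Curli and phage shock genes were lower in the deletion and higher again with the plasmid. Independent error of single probes in the shared deletion measurement goes against shuffles in which both ratios of a gene moved together among genes of like intensity: in 0 of 10000 did any of 27 lists reach the opposite medians of either group, measured on the spread of each list. With all 4 spots required, 1 shuffle reached those of curli and 71 those of phage shock. The other lists with opposite medians were reached more often in the main run. Among them were the tricarboxylic acid cycle list in 3.24% of shuffles, sigma S in 4.33%, ribosomal proteins in 5.45%, the biofilm-linked list in 8.68%, sugar uptake in 12.9% and ATP synthase in 25.9%. The rest were reached in most shuffles, such as the cyclic di-GMP list in 89.1%. For curli, an effect of the words CTCC or CCTC goes against the medians without such probes, the smallest of which was 1.13 in size. Of the measured members, 2 curli genes and 0 phage shock genes had such probes. For phage shock genes this run therefore could not decide, and other probe sequences were not tried. A region of the slide reaching 10 rows beyond the 2 groups, if probes were printed in the order of the tables, goes against the median of -0.30 over the 24 probes listed there (bootstrap interval from -0.46 to -0.18). Of these, 3 lay below -1, among them ymdA at -1.53 and ymdB at -1.11, listed near curli. A smaller region was not excluded, and the layout is not known. A culture of the deletion at another growth state stays open: it needs lower sigma S and higher ribosomal protein genes, and the sigma S median was -0.70 beside a ribosomal median of 0.49. The curli median was lower than in each of 10000 draws of 7 sigma S genes, the lowest of which was -1.14. The draws mixed separate genes, while curli genes are neighbours with their own regulator, csgD, so the draws do not decide this question. An effect of RodZ on curli may lie behind the pattern as well, and with 1 culture per strain it was not separated from the growth state.

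A different pattern appeared in 16 genes with log2 ratios of 3.05 to 5.70 for the RodZ plasmid strain over the wild type, among them ftsW at 5.70, lptD at 5.31, xanQ at 5.17, iap at 5.11 and dsrB at 4.80. A change of the whole genome region goes against their neighbours, whose median was -0.10 over 8 measured genes (bootstrap interval from -0.54 to 0.43), and 22 of 30 neighbours were not detected in that strain. The probes of 12 of the 16 held CTCC or CCTC, against 21.8% of the 1243 measured probes, and so did those of 9 of the 12 lowest genes. The words led among probes of odd number. Both sets of probes had been in view when the words were noticed, so the probes of even number are not a fully independent check. Among probes of even number those with the words had a mean log2 ratio higher by 0.27 (bootstrap interval from 0.026 to 0.52), so hybridisation to such probes may be a part of these values. The log2 ratios had an SD of 1.35 over probes with the words and 0.71 over the others, and transcription of these genes was not separately tested.

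The opposite ratios of the 2 comparisons were shared by neighbouring genes. The covariance of a gene's first ratio with its neighbour's second ratio was -0.17 over 451 pairs (bootstrap interval from -0.24 to -0.11), and 0.017 for genes 10 apart, which goes against independent error of single probes, since neighbours have separate probes. Log2 ratios of neighbours had a correlation of 0.35 for the deletion over the wild type, 0.26 for the RodZ plasmid strain over the deletion and 0.047 for the RodZ plasmid strain over the wild type, where it was 0.12 for genes 2 apart and 0.14 for genes 5 apart. A region of the slide cannot be told apart from operons here, because 100% of the neighbouring pairs were listed within 20 rows of each other and the layout is not given in the sources used here. Expression of whole operons in the deletion culture may account for the pattern, and was not tested on its own.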
